A study of Arabidopsis thaliana with 3 samples.

How the data were processed

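The labels describe small RNA from 3-week-old soil-grown seedlings under 16 h light and 8 h dark, extracted from whole cells, cytoplasm and nuclei in 3 biological replicates, of which replicates 2 and 3 pool 2 technical replicates. RNA was separated on a 15% denaturing gel, a slice of 18 to 28 nt was taken, and libraries were sequenced on Illumina Genome Analyzers. The deposited files list each distinct sequence with its count of reads, per the labels one file for each biological replicate. Adapter trimming, length limits and filters against the genome are not given in the sources used here; the values show lengths of 19 to 27 nt only and, in replicate 1 of each group, only sequences with an exact match to the genome.

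Replicate totals in reads were 11658491, 10811499 and 6891925 for whole cells, 17337006, 7256155 and 6329579 for cytoplasm, and 13790235, 8559817 and 5042030 for nuclei. At these depths the 95% Wilson interval of a share in 1 library reached at most 0.0428 percentage points to each side. Reads came from PCR without molecular identifiers, so such intervals, and the floor used for groups at 0, cover counting error only. The share of rRNA reads was 43.1, 25.2 and 20.6% in whole cell libraries, 24.2, 19.1 and 16.3% in cytoplasmic libraries and 64.9, 32.5 and 29.7% in nuclear libraries. Chloroplast reads made up 0.922, 3.92 and 3.19%, then 0.568, 4.23 and 4.30%, then 0.995, 7.61 and 6.67%.

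Of 13857364 distinct sequences, 10035588 matched TAIR10.1 exactly and 7503070 matched it at 1 place. Matches were found by exact lookup in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and numba 0.67.0, and permutation tests ran in scipy 1.17.1 and numpy. For locus counts a sequence with several matches was split evenly over them. For shares and sequence counts by class, all its reads went to a single class, the first it matched in a fixed order. That order was rRNA, tRNA, snRNA, snoRNA, miRNA genes, TAS, chloroplast, mitochondria, pseudogenes, protein coding, other noncoding and intergenic. An intergenic sequence therefore matched no annotated gene or pseudogene. Classes were taken from the TAIR10.1 annotation; 5000 bases after the 5.8S gene were counted as rDNA because the 25S gene is not annotated there. A hand-written list of 84 sequences named guides, stars and siRNAs, of which 83 were used; a second list named TAS loci, genes that yield phased siRNAs and inverted repeats.

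Single sequences were kept with at least 5 counts per 1e6 reads (CPM) in at least 3 libraries, loci and windows by the edgeR default filter. Windows were 1000 bp long and counted 24-nt reads with 1 match. Counts were fitted in edgeR 4.0.16 (R 4.3.3) with robust quasi-likelihood tests, 3 groups in 1 fit and TMM scaling, except that classes by length and first base used library totals. Adjusted p values are Benjamini and Hochberg values over all features of a fit, with 0.05 as the threshold, unless a list alone is named. The named genes follow 1 rule: features past the threshold whose 3 libraries of one group all lie above or below the 3 of the other, taken from the highest and lowest changes, plus a fixed list of guides, TAS loci and the windows with the most reads; the lists' other members are described as counts. Group lists, named-gene rules, the tests of the comparisons and most alternatives were chosen before the data were examined; the closing section names the tests chosen later.

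Shares of libraries were tested by an exact permutation of the F statistic over 3 groups of 3, which has 280 distinct partitions and a smallest p of 0.00357; within replicate numbers there are 36 and the smallest p is 0.0278. Sets of sequences were ranked with camera in limma 3.58.1 with a preset correlation of 0.01. Star and guide strands were compared by sign flips over pairs with 100000 draws. A group with a count of 0 was set to a floor of 3 counts over the group, which gives "at least" values.

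The numbers in the file names were checked as pairs. After removal of group means, libraries with the same number correlated at 0.384 to 0.841 over sequences and 0.592 to 0.906 over loci, and libraries with different numbers at -0.651 to 0.331 and -0.839 to 0.658. Removal of the mean of 3 libraries in itself pushes values of different numbers below 0. Over sequences, replicate 1 pairs stood at 0.705 to 0.841. Among replicates 2 and 3, same numbers stood at 0.384 to 0.666 and different ones at 0.115 to 0.331, a narrower contrast. Replicate number was therefore tried as a block.

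On simulated data with 200 changed features at a dispersion of 0.1, edgeR recovered 87.5% of 4-fold changes in sequences, 81.5% in loci and 44% in windows, and 2, 1.5 and 0% of 2-fold changes; at 4-fold, false calls made up 6.91, 2.98 and 4.35% of the calls. With 7 of 36 classes changed 2-fold at a dispersion of 0.02, 100% were recovered, but 2 further classes were called, so 22.2% of the calls were false. Means and library sizes were real, but the dispersions were set and not estimated from these libraries. Far more features passed in the data, 6111 of 22650 sequences and 6676 of 11884 loci, so these rates may not hold there.

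Alternatives were DESeq2 1.42.0, its size factors in edgeR, library totals, the replicate block, only the 2 groups compared, each library left out, filters at 1 and 20 CPM or none, sequences with 1 match, windows of 5000 bp, windows scaled to all reads, each distinct sequence counted once, and shares without the 10 most abundant sequences. Added after the data were seen were replicates 2 and 3 alone, reads that match the genome alone, and the alternatives of the set tests. Figures were drawn in matplotlib 3.10.9. Protein levels, AGO4 binding and mutants were not analysed here.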

Results

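Small RNAs of *Arabidopsis thaliana* Col-0 seedlings were compared between nuclear, cytoplasmic and whole cell extracts, with 3 biological replicates of each. Together the 9 libraries held 87676737 reads of 19 to 27 nt, from 5042030 in nuclear replicate 3 to 17337006 in cytoplasmic replicate 1. Changes are given in log2 with the standard error of the fit in brackets, and shares as mean ± SD, n = 3 libraries per group. The replicate 1 libraries of all 3 groups held only reads that match the genome, whereas 82 to 86% did in the others.

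Nuclear extracts held far fewer 24-nt reads and more 21-nt reads than cytoplasmic extracts. The 24-nt class, which holds the siRNAs that load AGO4-clade proteins and guide DNA methylation, made up 11.9 ± 1.46% of nuclear reads against 38.8 ± 2.07% of cytoplasmic reads. The 21-nt class, which holds most miRNAs and trans-acting siRNAs, made up 35.6 ± 6.77% against 18.9 ± 0.937%. The ratio of 24-nt to 21-nt reads was 0.349 ± 0.120 in the nucleus, 2.06 ± 0.151 in the cytoplasm and 2.76 ± 0.592 in whole cells, and it was lower in the nuclear library of each of the 3 replicate numbers. An exact permutation test over the 3 groups gave an adjusted p of 0.0161 for this ratio and for the 21-nt share, and 0.0445 for the 24-nt share. The first nucleotide moved too: 5' A, the base preferred by AGO4, opened 45.4 ± 2.87% of nuclear 24-nt reads, 58.2 ± 2.10% of cytoplasmic and 53.7 ± 1.13% of whole cell ones (exact permutation adjusted p = 0.0161). Within intergenic 24-nt reads, however, 5' A stood at 63.9 ± 3.57% in the nucleus and 64.2 ± 1.06% in the cytoplasm. With each distinct sequence counted once, the nuclear difference in 5' A over all 24-nt reads was far smaller and did not pass. Among 21-nt reads 5' U, the base preferred by AGO1, stood at 65.6 ± 3.20% in the nucleus, 62.7 ± 3.50% in the cytoplasm and 49.2 ± 3.23% in whole cells (exact permutation adjusted p = 0.0357). Nuclear replicate 3 also held few of the longest reads, with 0.298% of 26 nt and 0.122% of 27 nt against 7.70% and 3.60% in nuclear replicate 1. Without whole cell replicate 2 no share passed, and permuted within replicate numbers none of the 18 shares did. The test within replicate numbers permutes all 3 groups over 36 partitions, some of which only exchange whole cell and cytoplasmic libraries. A share that sets the nucleus alone apart can therefore fail in it however large the difference. The 24-nt share was lower in the nuclear library of each of the 3 replicate numbers.

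**Figure D1:**
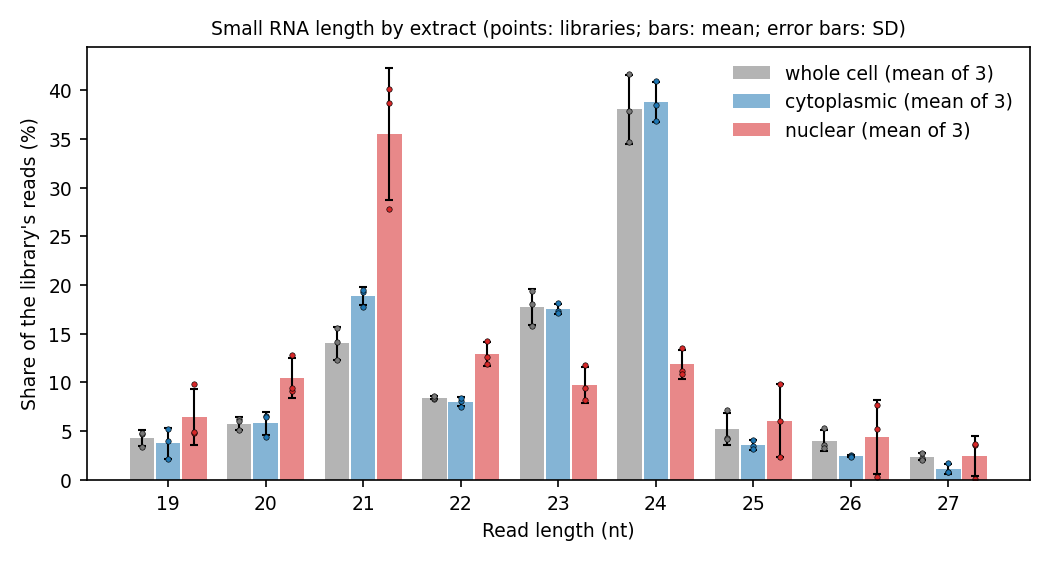
Share of reads of each length in whole cell, cytoplasmic and nuclear libraries; each point is 1 of 3 libraries per group.

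By length and first base together, 17 of 36 classes differed between nuclear and cytoplasmic libraries, 9 higher and 8 lower. All 4 classes of 24-nt reads and all 4 of 23-nt reads were lower in the nucleus. Among 24-nt reads the change was -2.07 (0.13) with 5' A, -1.85 (0.17) with 5' G, -1.08 (0.16) with 5' C and -0.97 (0.11) with 5' U. Higher classes included 21-nt reads with 5' A at +1.15 (0.16) and with 5' U at +0.99 (0.19), and 22-nt reads with 5' U at +0.93. The 21-nt reads with 5' C, at +0.53 (adjusted p = 0.0916), and with 5' G, at +0.25 (adjusted p = 0.134), did not pass. The 5' C class passed with replicate numbers in the fit (adjusted p = 0.0324) and without cytoplasmic replicate 3 (adjusted p = 0.0413).

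By annotation, the largest loss from nuclear libraries was of intergenic reads, 5.20 ± 0.630% against 30.8 ± 5.37% of cytoplasmic reads (exact permutation adjusted p = 0.0276). Pseudogenes, a class that holds many transposons, made up 1.88 ± 0.420% of nuclear and 8.83 ± 0.641% of cytoplasmic reads, with an exact permutation adjusted p of 0.0445. In the other direction, miRNA genes supplied 20.2 ± 5.52% of nuclear and 10.7 ± 1.28% of cytoplasmic reads, TAS loci 6.12 ± 1.72% and 3.49 ± 0.358%, and snoRNA genes, which guide modification of rRNA in the nucleolus, 0.374 ± 0.128% and 0.0360 ± 0.0023%. Fragments of rRNA took 42.4 ± 19.6% and 19.9 ± 4.0%, and over the 3 groups this share did not pass (exact permutation adjusted p = 0.202). Its nuclear values (29.7 to 64.9%) all lay above the cytoplasmic ones (16.3 to 24.2%), also within each replicate number. With each distinct sequence counted once 0 of the 18 shares passed, and the nuclear excess was 0.111 percentage points for miRNA genes and 0.218 for TAS loci, from 9.55 and 2.63. Of 18 shares, 13 passed over the 3 groups; without whole cell replicate 3 the count was 3, without cytoplasmic replicate 1 it was 8 and without cytoplasmic replicate 2 it was 5. For nuclear against cytoplasmic libraries alone the smallest exact p is 0.1.

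**Figure D2:**
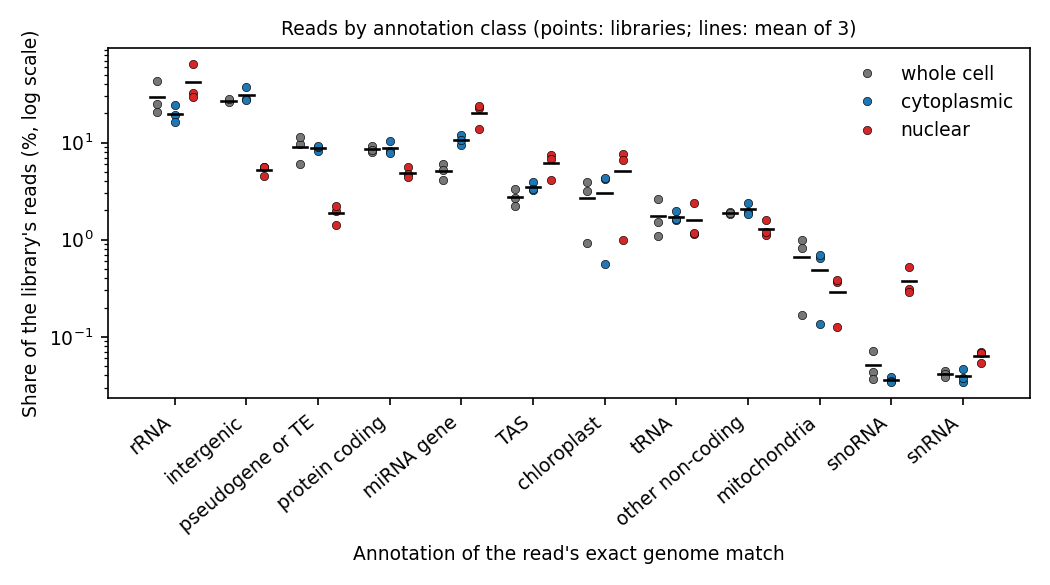
Shares of reads by annotation class in the 3 kinds of library.

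Mature miRNA guides made up 17.1 ± 4.56% of nuclear, 8.31 ± 1.20% of cytoplasmic and 3.60 ± 0.776% of whole cell reads, led by miR167a, which targets auxin response factors. Once scaled, none of 46 guides differed between nuclear and cytoplasmic libraries in edgeR (1 at an unadjusted p under 0.05; 2 with DESeq2), and their median change was +0.24. The median of all sequences was +0.54 with library totals as the scale. Of the 22650 sequences that set the TMM scale 14288 were rRNA, whose share was also higher in nuclei, so changes are relative to these. In simulation edgeR recovered 2% of 2-fold changes in sequences, so the lack of calls does not show an equal division. The 28 conserved guides had a median of +0.15 and the 18 guides found in Brassicaceae one of +0.39; these were +0.57 and +0.80 with library totals, and +0.69 (29 guides) and +1.10 (21 guides, 2 of them higher) with the filter at 1 CPM. The conserved median was -0.35 without nuclear replicate 3, -0.078 without nuclear replicate 2, -0.16 and -0.012 without cytoplasmic replicates 1 and 2, +0.55 without cytoplasmic replicate 3 and +0.48 without nuclear replicate 1. The Brassicaceae median was +0.61 and +0.95 without cytoplasmic replicates 2 and 3, and +0.74, +0.18 and +0.19 without nuclear replicates 1, 2 and 3. Single values were +0.02 (0.54) for miR159a, which targets MYB factors, -0.69 (0.69) for miR156a, which targets SPL factors, +1.03 (0.81) for miR166a, which targets HD-ZIP III factors, and +0.12 for miR403, which targets AGO2. Guides of the silencing pathway itself stood at +0.27 for miR168a (target AGO1), +0.54 for miR162a (target DCL1), -0.19 for miR390a and +1.28 (1.82) for miR173, the last 2 being triggers of TAS loci. The values of miR159a, miR403, miR168a, miR390a and miR173 changed sign in some fits with 1 library left out. The trans-acting siRNAs TAS1_siR255, at +0.73 (0.73), and TAS3_tasiR-ARF_D7, at +0.77 (0.86), did not pass either.

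Several miRNA star strands, the partners of the guides in the duplex, were lower in the nucleus. Of 22 star strands 7 were lower in nuclear libraries, as were 7 when adjusted over the list alone, and 9 of 22 had groups that did not overlap (chance gives 10% for 3 against 3). The lowest were miR157a* at -5.66 (1.54), miR168a* at -5.22 (1.04), miR172b* at -5.20 (1.18) and miR390a* at -4.79 (1.05). The other 3 were miR824* at -4.16 (0.99), miR396a* at -3.26 (0.79) and miR165a* at -2.86 (0.80). Reads of miR390a* went from 126 counts per 1e6 reads (CPM) in the cytoplasm to 4.54 in the nucleus, and those of miR396a* from 736 ± 202 to 77.1 ± 20.5. Over 22 pairs the star strand lay -1.90 (SE 0.557) below its guide in this comparison (permutation p = 0.00272). It was the lower strand in 13 pairs. That p treats pairs as independent, though all come from the same libraries, and does not measure spread between replicates. As a set in the rank test below, the star strands did not pass. The siRNA siR1003, which matches the genome at 205 places, was also lower at -3.40 (adjusted p = 0.0341). Without nuclear replicate 2 the count of star strands was 2 and without nuclear replicate 1 it was 4. The miR157a* call was also lost without cytoplasmic replicates 2 or 3 or nuclear replicate 3 (adjusted p = 0.0501, 0.0698, 0.0692), and that of miR165a* without cytoplasmic replicates 2 or 3 (0.0667, 0.0729). The siR1003 call was lost without whole cell replicate 2 (adjusted p = 0.0501), cytoplasmic replicates 1 or 3 (0.0613, 0.112) or nuclear replicates 1, 2 or 3 (0.104, 0.0789, 0.0842).

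**Figure D3:**
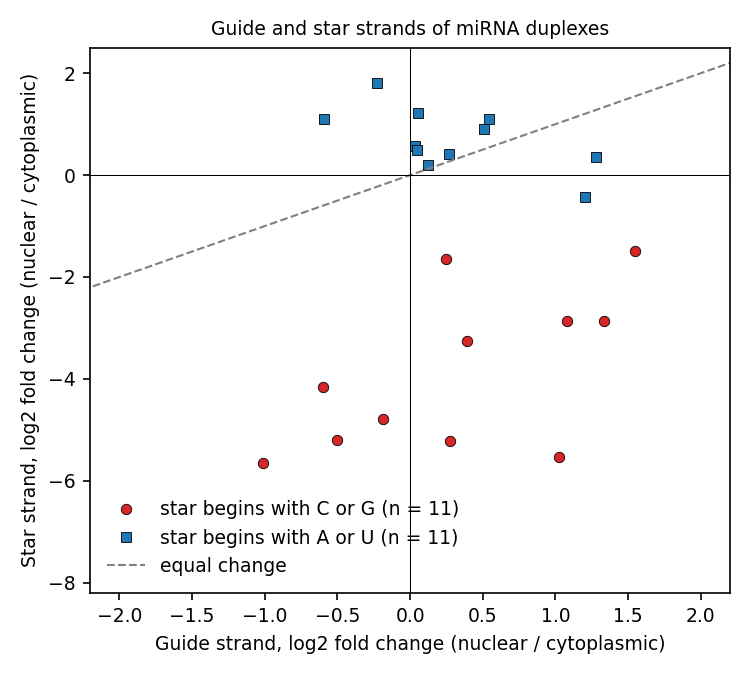
Nuclear against cytoplasmic log2 change of each star strand beside that of its guide, for 22 pairs.

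Across all single sequences, 6111 of 22650 differed between nuclear and cytoplasmic libraries, 1168 higher and 4943 lower (8634 at an unadjusted p under 0.05). Of 5562 sequences of 24 nt, 3249 were lower and 170 higher, with a median of -3.27; of 3628 sequences of 21 nt, 196 were lower and 208 higher, with a median of +0.62. Intergenic sequences were lower in 2237 of 2511 cases and higher in 5, pseudogene sequences lower in 492 of 642 and higher in 0. Of 14288 rRNA sequences 1127 were higher and 904 lower, and of 25 snoRNA sequences 14 were higher and 0 lower. On no list, TCAGCATTGATCCATCTCTGC, in a coding exon of AT1G72645 at the edge of the snoRNA gene AT1G09333, was highest at +7.86 (1.36), and GGGCACGGGCGTTAATGGACATGT, in an intron of AT5G48860, had no nuclear read and was at least 228-fold lower. With replicate numbers in the fit 10182 sequences passed, and without nuclear replicate 2 there were 3759.

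As sets, 21-nt sequences of TAS loci (adjusted p = 4.55e-05) and 21-nt sequences with each of the 4 first bases ranked higher in nuclear libraries, as did 22-nt sequences with 5' U. The 24-nt sets with 5' A and 5' G ranked lower, which made 8 of 13 sets past the threshold. The calls that held were those of the 24-nt sets with 5' A and 5' G, each at adjusted p = 0.00985 with an estimated correlation, of which the block by replicate number kept 5' A (0.0377) and lost 5' G (0.0611); the TAS set stood at adjusted p = 0.574 with an estimated correlation. The 21-nt set with 5' G had a median of +0.26 and a mean of -0.06. The 24-nt set with 5' C, which did not pass, had a median of -0.18 and a mean of -0.61 while its rank test pointed up. Star strands as a set did not pass. Conserved and Brassicaceae guides as sets did not pass, but ranked higher without nuclear replicate 1 (adjusted p = 0.0128 and 0.00591) and without cytoplasmic replicate 3 (0.0318 and 0.0338). Without nuclear replicate 3 the 21-nt sets with 5' C and 5' G did not pass (adjusted p = 0.0986 each).

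At annotated loci, small nucleolar RNA genes stood highest in the nucleus and pseudogenes lowest, while sources of trans-acting and phased siRNAs lay near protein coding genes. The median of all 11884 loci was -1.25 here, -0.49 with DESeq2 size factors and -2.35 with library totals. Relative to the first of these medians, snoRNA genes lay at +5.25, rRNA genes at +3.47, chloroplast genes at +2.96, protein coding genes at +2.81, snRNA genes at +2.79, TAS loci at +2.62, phased siRNA genes at +2.61, other noncoding genes at -0.58 and pseudogenes at -0.61. Few chloroplast genes passed, with 6 of 129 higher and 0 lower, and of 4 rRNA genes 2 were higher. Without this subtraction, medians were +0.76 for miRNA genes, +0.62 for mitochondrial genes and +0.54 for tRNA genes. In all 6676 loci passed, 2643 higher and 4033 lower; replicate numbers in the fit gave 10894. Without cytoplasmic replicate 2 the count was 4206, without cytoplasmic replicate 3 it was 4024 and without nuclear replicate 1 it was 4100.

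Of 8 TAS loci, whose transcripts yield trans-acting siRNAs, 6 were higher in nuclear libraries, and also 6 when adjusted over the list alone. They were TAS1B at +1.64 (0.41), TAS2 at +1.41 (0.44), TAS1A at +1.38 (0.36), TAS4 at +1.36 (0.46), TAS1C at +1.33 (0.39) and TAS3 at +1.05 (0.33). TAS1B went from 6913 ± 2221 to 21516 ± 6245 CPM. The other loci of the TAS3 family, AT5G49615 at +1.28 (adjusted p = 0.146) and AT5G57735 at +1.42 (adjusted p = 0.116), did not pass. With library totals as the scale 0 passed and TAS3 stood at -0.077, and without cytoplasmic replicates 2 or 3 the counts were 3 and 2. The TAS4 call was also lost without whole cell replicate 2 (adjusted p = 0.0508) or nuclear replicates 2 or 3 (0.0582, 0.114), that of TAS2 without nuclear replicate 2 (0.0623) and that of TAS3 without nuclear replicate 3 (0.0539).

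Of 21 genes that yield phased siRNAs, 20 were higher, with a median of +1.36, though 0 were with library totals. Examples chosen after their values were seen were AGO1 at +1.15 (0.31), the auxin receptor genes AFB2 at +1.26 (0.28) and TIR1 at +1.16, and the pentatricopeptide repeat gene AT5G41170 at +2.01. AFB3, at +0.63 (adjusted p = 0.172), did not pass, nor did the inverted repeat locus IR71, at +0.14 (adjusted p = 0.807).

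Of 215 snoRNA genes 211 were higher and 1 lower (AT2G05525 at -3.15, named after its value was seen), with a median of +4.0, and 190 were higher with library totals. The highest were AT1G08937 at +6.44 (1.20), AT5G01515 at +6.08 and AT2G04965 at +6.07 (0.71). Of 38 snRNA genes, which encode spliceosomal RNAs, 28 were higher; 18 passed without cytoplasmic replicate 2, and with library totals 2 were higher and 1 lower. Of 3901 pseudogenes 2078 were lower and 16 higher; 1386 passed without cytoplasmic replicate 3 and 1389 without nuclear replicate 1. Several loci had nuclear counts of 0 after reads with several matches were split and sums rounded. AT5G26090 was at least 6.60-fold lower (34 cytoplasmic counts). AT2G23540, which encodes a GDSL lipase, was at least 6.55-fold lower (31 counts) and AT1G33835 at least 6.23-fold lower (31 counts). Loci of 252 miRNA genes went both ways, 66 higher and 47 lower, and with library totals 3 higher and 60 lower; 75 passed without cytoplasmic replicate 3. Of 6016 protein coding genes 2199 were higher and 1562 lower, against 203 and 1938 with library totals; 2118, 2001 and 2024 passed without cytoplasmic replicate 2, cytoplasmic replicate 3 and nuclear replicate 1.

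**Figure D4:**
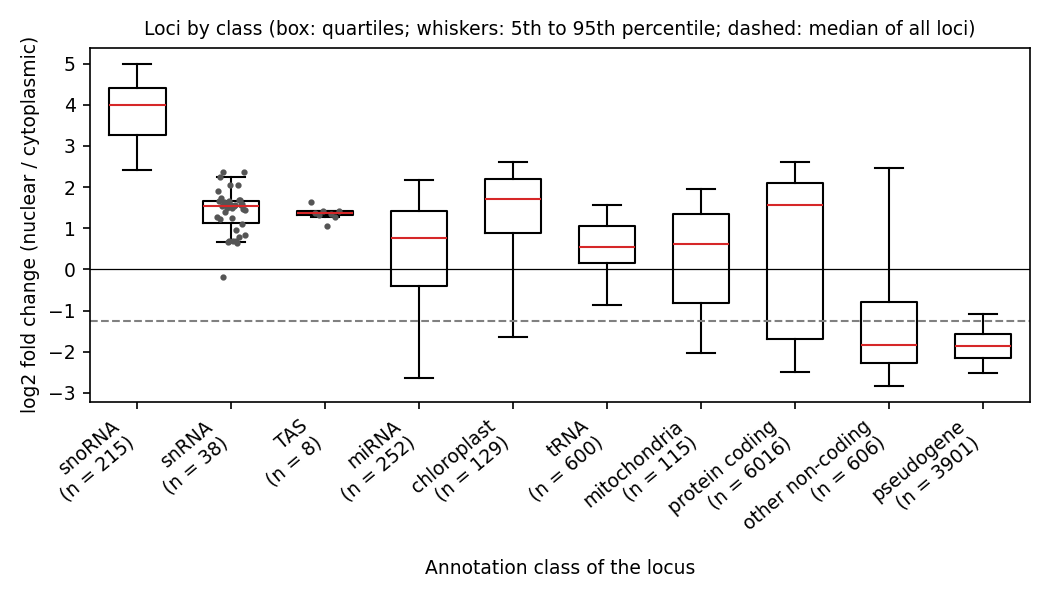
Nuclear against cytoplasmic log2 change of annotated loci by class; with library totals as the scale the median of all loci is -2.35, 0 of 8 TAS loci pass and TAS3 is at -0.077.

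Among 24-nt reads alone, scaled to each other over 1000-bp windows, 503 of 20920 windows departed from the common loss, 497 higher and 6 lower. Of 7606 intergenic windows 0 passed by edgeR (334 at an unadjusted p under 0.05; 17 with DESeq2), and 5 of 6754 pseudogene windows were higher and 4 lower. The other higher windows lay over snoRNA genes (84 of 90), snRNA genes (9 of 18), tRNA genes (15 of 78) and protein coding genes (342 of 5312). They also lay over other noncoding genes (32 of 921), miRNA genes (9 of 131) and rRNA genes (1 of 5). The highest were at the snoRNA gene AT4G39361, +8.87 (0.93), and at AT5G08180, which holds 3 snoRNA genes, +8.39 (0.94). Reads of snoRNA genes were higher in nuclei at other lengths too. Ratios of nuclear to cytoplasmic shares were 8.14 at 21 nt, 9.90 at 22 nt, 10.2 at 24 nt and 11.5 at the remaining lengths. Windows over snoRNA genes therefore need not hold siRNAs. The window with the most 24-nt reads, over MIR163, was +3.39 (0.48) relative to other windows, and +0.44, which did not pass, when scaled to all reads. With replicates 2 and 3 alone its adjusted p was 0.246. The listed miR163 guide is itself 24 nt long, and its reads were not taken out of this window. Scaled to all reads 228 windows were higher and 19016 lower. With replicate numbers in the fit 1357 windows passed, and without cytoplasmic replicate 2, cytoplasmic replicate 3 or nuclear replicate 1 the counts were 231, 257 and 189.

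Against whole cell libraries the nuclear libraries also held fewer 24-nt reads, and many guides were higher. Of 36 classes 7 were higher and 7 lower; 24-nt reads were -1.99 with 5' G and -1.92 with 5' A, and 21-nt reads +1.76 (0.20) with 5' U. Of 46 guides 16 were higher and 0 lower, or 7 when adjusted over the list alone, and 20 had groups that did not overlap (chance gives 10% for 3 against 3). The highest were miR164a, which targets NAC factors, at +3.80 (1.22), and miR399b, which targets the phosphate regulator PHO2, at +3.17 (0.90). TAS3_tasiR-ARF_D7, at +3.27, and TAS1_siR255, at +2.48, were higher and siR1003, at -3.95 (1.02), lower. Star strands went both ways: miR408* at +3.34 (1.04) and miR171a* at +2.87 were higher, and miR168a* at -3.21 (0.95), miR396a* at -2.21 and miR158a* at -1.89 lower, and 0 passed when adjusted over the list alone. The miR164a call was lost without nuclear replicate 3, at +1.73 (adjusted p = 0.167), and without nuclear replicate 2 (0.0510) or any 1 of the whole cell libraries (0.103, 0.101, 0.0905). That of miR399b was lost without whole cell replicates 1 or 2 or nuclear replicates 2 or 3 (adjusted p = 0.0723, 0.0821, 0.0672, 0.0608). The guide count was 28 with replicate numbers in the fit, 4 without nuclear replicate 2, 5 without nuclear replicate 3 or without any 1 of the whole cell libraries, and 9 without cytoplasmic replicate 1. The 5 star strands became 14 (6 higher, 8 lower) with replicate numbers in the fit and also with DESeq2, 0 without whole cell replicate 2, 4 higher and 0 lower without nuclear replicate 1, 1 without whole cell replicate 3, nuclear replicate 2 or nuclear replicate 3, 2 without whole cell replicate 1 and 3 without cytoplasmic replicate 1 or 2. The siRNA calls fell from 3 to 0 without whole cell replicate 3 and to 1 without whole cell replicate 1 or nuclear replicate 2.

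At loci, 4838 of 11884 differed between nuclear and whole cell libraries, 1293 higher and 3545 lower, around a median of -1.09 that was -0.39 with DESeq2 size factors and -2.32 with library totals. Higher were 202 of 215 snoRNA genes, 21 of 21 phased siRNA genes and 6 of 8 TAS loci (7 when adjusted over the list alone), TAS1B at +2.96 (0.43) among them; lower were 1880 of 3901 pseudogenes. With library totals 6 phased siRNA genes and 2 TAS loci passed, and without whole cell replicate 2 there were 3 TAS loci. The highest loci were the noncoding genes AT3G02832 at +6.74 (1.02) and AT5G09505 at +6.42 (0.96) and the snoRNA gene AT2G35744 at +6.31 (0.68). The lowest, AT5G33380, was at least 7.19-fold lower, a call lost without whole cell replicate 2 (adjusted p = 0.0514) or 3 (adjusted p = 0.0520). The count was 10649 with replicate numbers in the fit and 2823 with the 2 groups alone. Without whole cell replicates 1, 2 or 3 it was 8182, 2914 and 2930, and without nuclear replicate 1 it was 3217, and without nuclear replicate 2 there were 793 higher and 2284 lower; pseudogene counts then were 3010, 1160, 1117, 1175 and 1184.

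Cytoplasmic and whole cell libraries differed in no guide, class or locus by edgeR, although guides leaned upward in the cytoplasm. The median guide was +1.62 and 17 of 46 had groups that did not overlap (chance gives 10% for 3 against 3); 13 stood at an unadjusted p under 0.05, 9 passed with DESeq2 and 8 with replicate numbers in the fit. When adjusted over the list alone 2 were higher, miR157a at +2.67 (0.54) and miR447a at +2.36 (0.50), which were named after their values were seen. Of the 36 classes 2 reached an unadjusted p under 0.05 and 1 passed with DESeq2; 21-nt reads with 5' U stood at +0.77 (adjusted p = 0.0979). Of 11884 loci 458 reached an unadjusted p under 0.05, where 594.2 are expected by chance, 9 passed with DESeq2, and 993 passed with replicate numbers in the fit. Without nuclear replicate 1 the count of classes was 1 and without nuclear replicate 3 it was 2.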

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

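Tests on replicates 2 and 3 alone, on reads that match the genome alone, and all alternatives of the set tests were chosen after the data were seen. Counts, single calls, some shares and the sign of some values moved with the settings below; the cause was not tested. With replicates 2 and 3 alone the shares have values but no test, since the smallest possible p is 0.0667. All lengths in place of 18 to 28 nt was not run as a separate setting, because the files hold 19 to 27 nt and it moves nothing.

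With replicate numbers as a block, counts past the threshold were 10182 single sequences, 28 guides against whole cell in the nucleus and 8 in the cytoplasm, 10894, 10649 and 993 loci (nuclear against cytoplasmic, nuclear against whole cell, cytoplasmic against whole cell) and 1357 windows; miR168a stood at -0.086 and miR173 at -0.11, star strands between nucleus and whole cell numbered 14, and the block moved none of the other counts of guides, classes or sets by more than 1.5 times. Permuted within replicate numbers, 0 shares passed at unmoved differences (nuclear minus cytoplasmic, percentage points): 21 nt 16.7, 24 nt -26.9, 5' A in 24 nt -12.8, 5' U in 21 nt 2.86, snRNA 0.0242, snoRNA 0.338, miRNA genes 9.55, TAS 2.63, pseudogenes -6.94, protein coding -3.85, other noncoding -0.756, intergenic -25.6, and -1.71 for the ratio of 24 nt to 21 nt. Their adjusted p then lay between 0.0714 and 0.1. Over 36 partitions of 3 groups this test has little power where only the nucleus stands apart, so no conclusion is drawn from it.

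With each distinct sequence counted once, 0 shares passed as well: 21 nt 13.1, 24 nt -23.6, the ratio -5.34, 5' A -1.49, 5' U 6.05, snRNA 0.101, snoRNA 0.440, miRNA genes 0.111, TAS 0.218, pseudogenes -8.27 and intergenic -20.3, while tRNA (0.275), mitochondria (0.121), protein coding (12.5) and other noncoding (0.0088) turned positive. The tRNA share was 0.0459 without the 10 most abundant sequences, the TAS share 3.09 with reads that match the genome alone, and the 5' U share 6.48 with replicates 2 and 3 alone.

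Filters gave 1364 single sequences at 20 CPM and 38698 at 1, where 2 guides passed between nucleus and cytoplasm and miR390a stood at +0.23. DESeq2 gave 2 guides there, 9 guides, 1 class and 9 loci between cytoplasm and whole cell. The 2 compared groups alone gave 9 guides and 2823 loci between nucleus and whole cell and 1 class between cytoplasm and whole cell. With no filter 12 loci passed between cytoplasm and whole cell, and 3031 windows. Windows of 5000 bp gave 796, and windows scaled to all reads 19244. Replicates 2 and 3 alone gave 7820 loci between nucleus and whole cell and 6 loci and 1 class between cytoplasm and whole cell. Of the sets 2 held with an estimated correlation, and 1, the 24-nt set with 5' A, with the block as well.

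Some single values between nucleus and cytoplasm changed sign. With replicates 2 and 3 alone miR159a was -0.015; with library totals miR390a was +0.27 and TAS3 -0.077; and scaled to all reads the TAS1C window was -2.30. The window over AT3G27140 was -0.090 with library totals, -0.16 with no filter, -2.79 scaled to all reads and -0.011 with replicates 2 and 3 alone.

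Leaving out 1 library at a time, counts ranged over 3759 to 6093 single sequences, 4 to 18 guides between nucleus and whole cell, 0 to 2 classes between cytoplasm and whole cell, 4024 to 7985 loci between nucleus and cytoplasm, 2914 to 8182 loci between nucleus and whole cell, 189 to 630 windows and 0 to 12 shares. The share differences ranged over 14.4 to 20.6 for 21 nt, -27.9 to -25.8 for 24 nt, -1.80 to -1.66 for the ratio, -14.3 to -11.4 for 5' A, 1.28 to 4.74 for 5' U, -0.573 to 0.0604 for tRNA, 0.0215 to 0.0289 for snRNA, 0.265 to 0.382 for snoRNA, 7.70 to 12.7 for miRNA genes, 1.99 to 3.61 for TAS, -7.31 to -6.70 for pseudogenes, -4.34 to -3.03 for protein coding, -0.906 to -0.589 for other noncoding, -27.3 to -22.5 for intergenic and -4.72 to 5.67 for reads with no match. Differences for rRNA, chloroplast and mitochondria, which did not pass, kept their sign but moved more in proportion than those of 21 nt and 24 nt. Values ranged over -0.24 to 0.39 for miR159a, -0.19 to 0.89 for miR168a, -0.41 to 0.60 for miR403, -1.02 to 0.97 for miR390a, -1.79 to 1.92 for miR173, -0.045 to 0.31 for the AT3G27140 window, and -0.28 to -0.057 for the median of the 24-nt set with 5' C.

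Under the settings other than leaving out 1 library at a time, which include those that drop a group or replicate 1 of each group, 246 values of named sequences kept their direction and side of the threshold, 19 no longer passed and 5 changed sign. Among named loci 167 kept them, 13 no longer passed, 8 newly passed and 1 changed sign. Among named windows 59 kept them, 16 no longer passed, 1 newly passed and 5 changed sign. With 1 library left out at a time, 203 values of named sequences kept them, 64 no longer passed and 12 changed sign. Among named loci 194 then kept them and 22 no longer passed. Among named windows 56 then kept them, 24 no longer passed and 1 changed sign.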

Other observations

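The split of star strands by first base, and the tests of dilution in the nuclear libraries, of 24-nt intergenic reads, of low star counts, of cloning bias and of the whole cell libraries were chosen after the results they measure had been seen. Nuclear libraries held few 24-nt intergenic reads, and the first bases of those reads differed from cytoplasmic ones: among intergenic 24-nt reads, 5' U opened 28.5 ± 3.92% in nuclear and 14.4 ± 0.488% in cytoplasmic libraries, 5' G 6.07 ± 1.06% and 16.7 ± 1.30%, and 5' C 1.60 ± 0.174% and 4.61 ± 0.320% (exact p = 0.1 each, the smallest possible). These shares weigh each sequence by its reads. Of 102 intergenic 24-nt sequences with 5' U that were tested singly, 90 were lower in nuclei and 0 higher. Their median was -4.61, against -3.84 over 1520 with 5' A, so single sequences with 5' U were not spared. For every intergenic 24-nt read there were 6.87 ± 1.62 miRNA guide reads in the nucleus, 0.408 ± 0.0509 in the cytoplasm and 0.198 ± 0.0470 in whole cells. By group means miR167a was the most frequent sequence (miR159a led in whole cell replicate 2 and cytoplasmic replicate 2), at 7.19% of nuclear, 2.29% of cytoplasmic and 0.869% of whole cell reads. For each 100 guide reads there were 0.920 ± 0.277 star reads in the nucleus and 3.05 ± 0.793 in the cytoplasm.

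The lower 24-nt share in nuclear libraries was set against 3 technical explanations. Gel slices with less of the 24-nt range would have lowered 24-nt rRNA fragments as well, but their median was +0.44 over 1804 sequences against -4.11 over 2007 intergenic ones, a difference of 4.55. Dilution by abundant fragments would have left intergenic 24-nt reads per guide read equal, but the nuclear ratio was at most 0.0760 of the cytoplasmic one. Without the 10 most abundant sequences the difference in share was still -27.1 percentage points. These values leave open both a lower content of 24-nt siRNAs in nuclei and their loss during extraction, which may be told apart by siRNAs added to nuclei before extraction; no such test was possible here.

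Star strands with 5' C or G were the ones lower in nuclear libraries: 7 of 11 passed, with a median of -4.16, against 0 of 11 with 5' A or U (edgeR; 0 at an unadjusted p under 0.05; DESeq2 gave 11 lower over all 22), a median of +0.57 and a difference of -4.73, which has no test here because the split was drawn from these strands. The same lean by first base was looked for in sequences on no list. In 21-nt sequences the difference was -2.17 at TAS loci and -3.64 at miRNA genes (permutation p = 1e-05 for each, the smallest possible). That p treats sequences as independent, though many share loci and all share libraries, and does not measure spread between replicates. At TAS loci the median was -4.15 with 5' G (14 of 16 lower) but -0.72 with 5' C (2 of 22 lower). Only exact listed sequences were left out, so the miRNA gene set can hold shifted forms of the listed strands. It is not independent of them. In intergenic 24-nt reads the higher nuclear to cytoplasmic ratio of 5' C and G was 0.363 of the lower one of 5' A and U. The lean varied with the source. Over all 24-nt reads the ratio was 0.474 with 5' C and 0.238 with 5' A. In tRNA fragments of 24 nt it was 1.31 with 5' G and 0.570 with 5' A. By reads, the lean was seen in 24-nt pseudogene reads (0.0598 with 5' C and 0.0545 with 5' G against 0.127 with 5' A and 0.237 with 5' U). More weakly, it was seen in rRNA (1.63 and 1.43 against 2.63 and 2.07). By single 24-nt sequences, pseudogene medians were -5.31 with 5' G and -3.94 with 5' C against -3.74 with 5' A and -3.76 with 5' U. Intergenic medians were -5.51 with 5' G and -5.90 with 5' C against -3.84 with 5' A and -4.61 with 5' U. Low counts alone did not account for the split of the stars. With at least 20 cytoplasmic CPM, the 10 with 5' C or G, at most -1.49, all lay under the 7 with 5' A or U, at least -0.44 (medians apart by -4.88). These stars are among those from which the split was drawn, and the cut was chosen afterwards. GC content was not tested in the stars. In 21-nt sequences of TAS loci and miRNA genes on no list the difference was -2.95 at equal GC count. That value argues against GC content as the whole cause in those sequences. A cloning bias was too weak to be the whole cause, at -0.30 in 2130 21-nt rRNA sequences, while a small part of it stays open. The lean was relative, since intergenic 24-nt reads with 5' A also had a nuclear to cytoplasmic ratio of 0.120, and its cause stays open, since protein binding was not measured.

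Guides stood higher in both fractions than in whole cell libraries, with 16 calls in the nucleus and, in the cytoplasm, 0 by edgeR (13 at an unadjusted p under 0.05), 9 by DESeq2 and 8 with replicate numbers in the fit. Dilution of whole cell libraries would have lifted 24-nt intergenic sequences alike, but in the cytoplasm these lay -1.80 below the guides. A plain mix of both fractions would put the whole cell ratio of guide to intergenic 24-nt reads between the others, but the cytoplasmic ratio was at least 1.61 times the whole cell one, and the nuclear one higher still. No biological explanation was tested; a difference in RNA extraction between whole cells and fractions may remain, and it is untested.

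Other splits of 6 libraries were too few for a share under 0.05: only 4 of the 10 part all 3 replicate numbers. The real split was the 1 split with as many calls for 6111 sequences, 17 classes, 6676 loci and 503 windows (nuclear against cytoplasmic) and for 16 guides, 14 classes and 4838 loci (nuclear against whole cell), with 0 as the highest of the others. All 4 gave 0 for guides between nucleus and cytoplasm and for guides, classes and loci between cytoplasm and whole cell by edgeR, where unadjusted counts were 1, 13, 2 and 458 and DESeq2 gave 2, 9, 1 and 9. Splits that part 1 pair gave up to 1522 loci between nucleus and whole cell, 19 loci and 1 class between nucleus and cytoplasm, and they set libraries of different replicate numbers against each other.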
